A study of Rattus norvegicus with 144 samples.

How the data were processed

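The analysis started from the authors' deposited table, which holds 45785 genes for 144 libraries, and from the sample labels. Per the file headers, each library has a column of whole-number counts per gene and a column of FPKM. The authors scaled FPKM by gene length and by library total, and the deposited values equalled count over length and total up to a constant of 0.944 to 1.04 per library in genes with at least 100 counts. Per the file headers the deposited comparisons give log2 fold changes, p-values and adjusted p-values by the authors, whose test is not given in the sources used here. The deposited group means of those comparisons are normalized counts by the authors, with a normalization that is not stated. FPKM were not used here beyond this check, and the authors' comparisons were only set beside the calls made here.

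The submitters' processing notes name fastp, without a version, and HISAT2 2.0.5. What each was used for, the read counter and the genome build are not given in the sources used here. Of the gene identifiers 45780 occur in the RefSeq gene table, and 45774 have the same coordinates in the rat assembly GRCr8. Per the labels the tissue is the anterior cingulate cortex, the RNA is total RNA, cDNA was primed with random hexamers and the libraries do not keep strand. Genes that overlap on opposite strands, such as LOC134484082 and Xist or LOC100912991 and Pbdc1, and genes with near-identical copies or pseudogenes therefore have uncertain counts. The table has 0 mitochondrially encoded genes, so that list could not be tested, and 91 symbols are shared by several genes. Nucleus accumbens was not analysed here. The labels give 1 batch date and no litter, animal or pairing, so no such term could be fitted. Replicates are numbered in the order of the labels.

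The comparisons, the gene lists, the naming rule and the alternatives were fixed before the data were examined, for 33 comparisons. The 6 comparisons over both sexes and ages and the alternatives that leave out 5 libraries were added after the files had been read. Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and dispersions were estimated by estimateDisp and glmQLFit with the robust option. Contrasts were tested by glmQLFTest with Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 are given as called. The standard error of a log2 fold change is its absolute value over the square root of F. Age, sex and their interactions were contrasts in a fit of all 144 libraries with 24 groups of equal weight. The 24 exposure comparisons were contrasts in 4 fits, 1 for each sex and age, with 6 treatment groups each. PAE, PF and FCL were averaged over water and alcohol, and alcohol and water over the 3 prenatal conditions.

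Means and SD are over the libraries of a side, in CPM (counts scaled to the library total) after TMM scaling for genes in a comparison and without that scaling for values of single libraries. Of 36 gene lists written, 35 had at least 3 tested members, and each was tested by camera of limma 3.58.1 with a preset correlation of 0.01 between genes and adjustment over the lists. Camera with an estimated correlation and fry were the alternatives. Named genes are the 12 called genes with a symbol and the smallest p in each direction, up to 4 called members of a called list and up to 2 of any other list. Where no gene was called, the 3 with the smallest p were named as not past the threshold. Xist, Ddx3y, Kdm5d, Eif2s3y and Uty were read in every library, and a gene called for an exposure in more than 1 sex and age group would have been named. From the named genes the text gives a choice, and some are not reported here.

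Each count of called genes was repeated with DESeq2 1.42.0, with RLE scaling, without the low-count filter, with 2 surrogate variables from sva 3.50.0 and without the 5 libraries whose marker genes, gene detection or correlation stood apart. The exposure comparisons were repeated in the fit of 144 libraries and with each library left out, and the age and sex comparisons with only PF VEH and FCL VEH. The interactions of sex with an exposure were also fitted within 1 age. Labels were reassigned at random in 50 splits per exposure comparison and 21 splits for the others, the real labels being 1 of them. The pipeline was tested on simulated data, with 200 genes changed by 1.25-, 1.5- or 2-fold in negative binomial counts. Of 366 pairs of libraries within a group, 0 were identical. Groups of values per library were examined with Dixon's test. All libraries were kept.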

Results

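Gene expression in the anterior cingulate cortex, a midline region of the frontal cortex, was measured by RNA sequencing in 69 libraries from female and 75 from male Long Evans rats. The rats belonged to 24 groups, given by sex, by prenatal condition, by adolescent condition and by age at collection. Prenatally, rats were exposed to ethanol (PAE), belonged to a pair-fed group (PF), in which intake is matched to that of ethanol-exposed dams, or to a group with a freely chosen liquid diet (FCL). In adolescence they received alcohol (AAE) or water (VEH), and brains were taken at postnatal day 42, shortly after the last adolescent exposure, or in adulthood at postnatal day 90. The groups held 4 to 7 libraries, and the sexes and ages came to 34 adolescent females, 35 adult females, 39 adolescent males and 36 adult males. Total counts ran from 10.6 M to 34.4 M per library, and between 15631 and 28008 of 45785 genes had at least 1 count (median 23116). The labels name no litter and do not say how many rats stand behind the libraries of a group, so that p-values measure the spread between these libraries.

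The sex-linked genes were read in every library first, because they check the labels. Xist, the RNA that silences an X chromosome in female cells, lay at 515 ± 89.9 CPM (SD, n = 66) in libraries labelled female. It lay at 4.95 ± 11.8 (n = 73) in those labelled male. The 4 Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty summed to 1.42 ± 2.82 and 192.8 ± 16.8. These means leave out 5 libraries that stood apart. Replicate 4 of the female PF AAE adolescents held 0.993 CPM of Xist and 0.331 of the Y-linked genes, and replicate 4 of the male PAE VEH adolescents held 379 and 27.1. Replicate 6 of the female PF VEH adults had the fewest genes detected, 15631, and the highest Xist, 1302 CPM. Omp and Cyp2a3, which are made in the olfactory mucosa, stood at 258 and 2206 CPM in replicate 1 of the female FCL AAE adults, and at 398 and 2371 in replicate 6 of the male PF VEH adolescents. All 5 stayed in under their labels, and every count of changed genes was also made without them. Others still reached 95.9 CPM of Xist and 36.1 of Cyp2a3 in males and 13.7 of Y-linked genes in females.

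**Figure D1:**
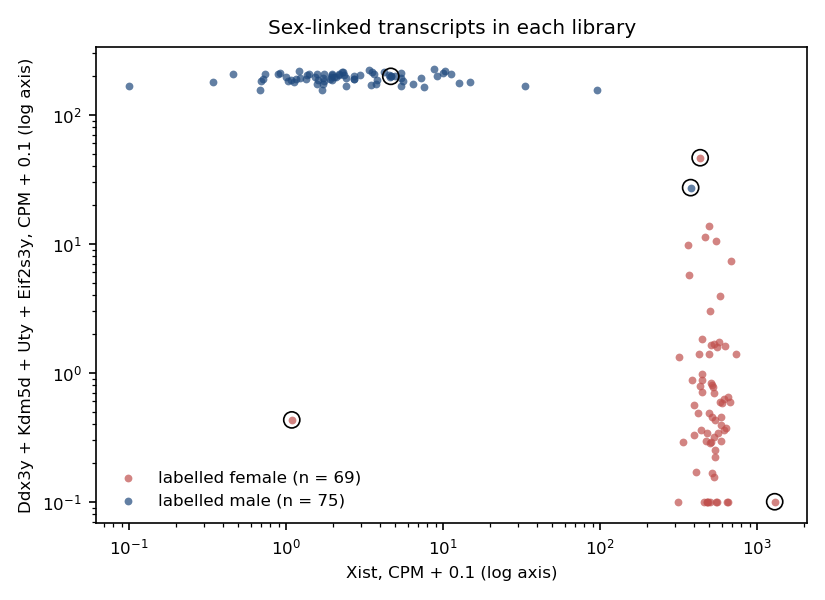
Xist against the sum of 4 Y-linked genes, both in CPM on log axes, with 1 point per library coloured by labelled sex and the 5 libraries named in the text circled. The other female libraries lie at 313 to 738 CPM of Xist, and the other male libraries at 154.4 to 228 CPM of the Y-linked genes.

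The comparison of adults with adolescents asks how the anterior cingulate cortex changes between postnatal days 42 and 90, averaged over the 6 treatment groups of a sex. In females, Jade2, which codes for a chromatin-associated ubiquitin ligase (chromosome 10, 36576187 to 36625129, GRCr8), rose from adolescence to adulthood by 0.46 ± 0.04 on the log2 scale (standard error), 97.0 ± 8.86 CPM (SD, n = 35) against 70.7 ± 10.8 (n = 34). Qdpr, the enzyme that regenerates tetrahydrobiopterin for monoamine synthesis, rose by 0.97 ± 0.10, 142 ± 42.96 against 71.8 ± 25.2 CPM. Bdh1, the mitochondrial hydroxybutyrate dehydrogenase of ketone body metabolism (chromosome 11, 82806125 to 82848133), changed by -0.36 ± 0.03, 45.2 ± 4.94 against 58.01 ± 4.84 CPM, and Apc, a brake on Wnt signalling, by -0.44 ± 0.05, 468 ± 75.2 against 638 ± 73.9 CPM. The imprinted gene Mkrn3, which restrains the onset of puberty, changed by -1.34 ± 0.17, from a mean of 1.46 to 0.602 CPM. The adjusted p of these genes was 2.76e-18, 2.37e-14, 2.70e-16, 5.55e-13 and 3.32e-09 in edgeR's quasi-likelihood test.

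The remaining genes with the smallest p that were higher in adult females were Epdr1 (0.35 ± 0.03), Ezh1 (0.23 ± 0.02), Epb41l4b (0.35 ± 0.04), Itpr1 (0.34 ± 0.04) and Cbx7 (0.36 ± 0.04). They were followed by Ppt1 (0.25 ± 0.03), Hapln4 (0.48 ± 0.06), Crebrf (0.24 ± 0.03), Anxa4 (0.43 ± 0.05) and Upf2 (0.29 ± 0.04). Ezh1 and Cbx7 belong to the Polycomb repressors of chromatin, Itpr1 is a calcium channel of the endoplasmic reticulum, Ppt1 is a lysosomal thioesterase and Hapln4 is a link protein of perineuronal nets. Those that were lower were Nras (-0.27 ± 0.03), Ifnar1 (-0.22 ± 0.02), Dcaf7 (-0.22 ± 0.02), Gnb4 (-0.45 ± 0.05) and Rras2 (-0.47 ± 0.05). They were followed by Aacs (-0.37 ± 0.04), Vopp1 (-0.22 ± 0.03), Met (-0.47 ± 0.06) and Emid1 (-0.48 ± 0.06). Nras and Rras2 are small GTPases, Ifnar1 is a subunit of the type I interferon receptor and Met is the receptor of hepatocyte growth factor. In all, 1817 of 20137 genes passed the threshold in females, 969 higher and 848 lower in adults.

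In males, the same comparison gave 2630 genes, 1399 higher and 1231 lower in adults, of which 286 differed by more than 1.5-fold. Qdpr rose by 0.98 ± 0.09, 140.4 ± 50.2 CPM (SD, n = 36) against 70.8 ± 11.8 (n = 39), and Nat8f3, an acetyltransferase gene, by 0.74 ± 0.08, 86.5 ± 18.1 against 52.5 ± 11.5 CPM. Gpr17, a receptor of committed oligodendrocyte precursors, changed by -0.88 ± 0.09, 64.2 ± 14.4 against 119.6 ± 33.8 CPM, with an adjusted p of 2.35e-13. Other genes with the smallest p that were higher in adults were Aadat (0.83 ± 0.09), Prnp (0.19 ± 0.02), Fbxo33 (0.28 ± 0.03), Dkk3 (0.28 ± 0.03) and Ptk2b (0.28 ± 0.03). Those lower were Pnlip (-1.14 ± 0.12), Adam19 (-0.51 ± 0.06), Cyp51 (-0.29 ± 0.03), Aco1 (-0.26 ± 0.03) and Nav3 (-0.30 ± 0.04). Aadat makes kynurenic acid, Prnp is the prion protein, Cyp51 is an enzyme of sterol synthesis, Aco1 is the iron-sensing cytosolic aconitase and Nav3 is expressed in growing neurons. Jade2 (0.45 ± 0.04), Epdr1 (0.39 ± 0.03), Bdh1 (-0.32 ± 0.03), Apc (-0.45 ± 0.05) and Mkrn3 (-1.36 ± 0.17) were again among the called genes. The 41 genes named for the smallest p in either sex all passed the threshold in both sexes with the same sign.

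**Figure D2:**
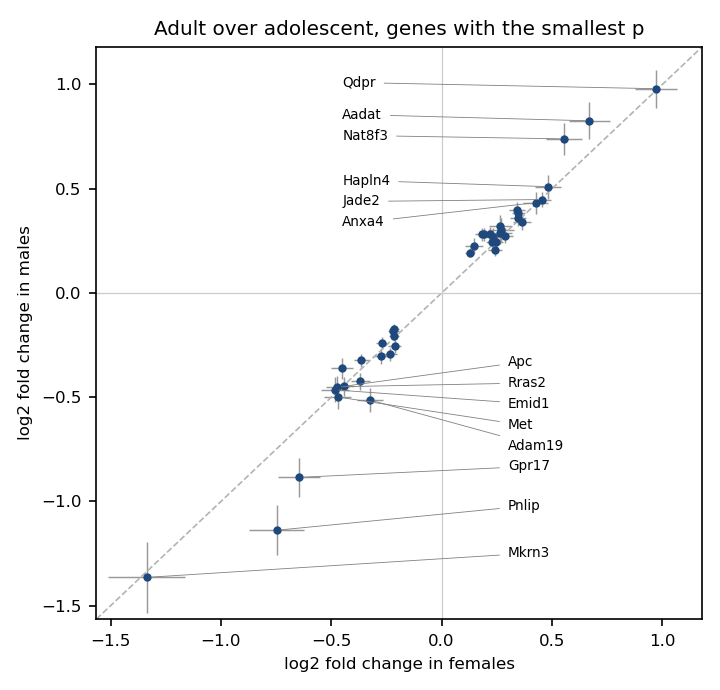
Log2 fold change of adults against adolescents in females (x axis) and males (y axis) for the 41 genes with the smallest p in either direction in either sex, with 1 point per gene and bars of 1 standard error. All 41 points lie in the quadrants of equal sign, from Mkrn3 at -1.34 in females and -1.36 in males to Qdpr at 0.97 and 0.98.

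Genes induced by neuronal activity were higher in adults of both sexes. All 17 immediate early genes had a positive log2 fold change in females, and 12 rose past the threshold, and 12 when adjusted over the list alone. Their median was 0.53 (camera's adjusted p = 4.38e-18, adjusted p = 0.0243 with an estimated correlation). In males 17 of 17 were higher and 15 passed, with 15 adjusted over the list alone and a median of 0.66 (camera's adjusted p = 3.27e-23, adjusted p = 0.0107 with an estimated correlation). Arc, which regulates glutamate receptors at synapses, rose by 1.04 ± 0.17 in females, 122 ± 62.04 CPM (SD, n = 35) against 59.8 ± 38.2 (n = 34), and by 1.29 ± 0.17 in males. Npas4, a transcription factor of activity-dependent inhibition, rose by 0.98 ± 0.15 and 1.15 ± 0.15 in females and males. Further members were Junb (0.66 ± 0.11) and Dusp1 (0.55 ± 0.10) in females and Fosb (1.10 ± 0.13) and Egr2 (1.67 ± 0.22) in males.

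Genes of immature neurons and axon growth were lower in adults. In females 14 of 15 had a negative fold change, 8 fell past the threshold and 9 did so when adjusted over the list alone (camera's adjusted p = 1.17e-08, adjusted p = 0.0128 with an estimated correlation). In males 13 of 15 were lower, 7 passed and 8 did so adjusted over the list alone (camera's adjusted p = 2.07e-05, adjusted p = 0.0551 with an estimated correlation). They included Marcksl1, an actin regulator of growing neurites, at -0.54 ± 0.08 in females and -0.56 ± 0.07 in males, and Dpysl5, a collapsin response protein, at -0.35 ± 0.06 and -0.24 ± 0.05. The transcription factor Sox4 stood at -0.27 ± 0.05 and -0.23 ± 0.05 and the tubulin Tuba1a at -0.22 ± 0.04 and -0.22 ± 0.04. Cell cycle genes went the same way, with 13 of 14 lower in females, 2 past the threshold and 3 adjusted over the list alone, and 14 of 14, 5 and 8 in males. The camera calls of this list gave adjusted p = 0.175 and adjusted p = 0.0741 with an estimated correlation. Top2a, the topoisomerase of dividing cells, changed by -1.04 ± 0.22 in females and -1.04 ± 0.21 in males, and the spindle motor Kif11 by -0.61 ± 0.20 and -0.93 ± 0.19.

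Oligodendrocyte genes were lower in adults, with more calls in males. Of 16 myelin genes, 15 were lower in adult males, 10 fell past the threshold and 13 did so adjusted over the list alone (median -0.61, camera's adjusted p = 2.44e-11, adjusted p = 0.149 with an estimated correlation). In females 14 were lower and 2 passed, with 6 lower and 1 higher adjusted over the list alone (camera's adjusted p = 0.0327, adjusted p = 0.732 with an estimated correlation). Ugt8, which makes the myelin lipid galactosylceramide, changed by -0.71 ± 0.16 in females and -1.10 ± 0.16 in males. Precursor genes were lower for 8 of 10 in females, with 3 called and 3 adjusted over the list alone (adjusted p = 0.277 with an estimated correlation). In males 9 of 10 were lower, with 7 and 8 (adjusted p = 0.0551 with an estimated correlation). Enpp6, a marker of newly forming oligodendrocytes, changed by -1.03 ± 0.17 and -1.11 ± 0.16, and Pdgfra, the growth factor receptor of precursors, by -0.27 ± 0.07 in males. Cholesterol synthesis genes were lower for 19 of 19 in females, 6 called and 7 adjusted over the list alone (adjusted p = 0.175 with an estimated correlation). In males 18 of 19 were lower, 11 of them called by either adjustment (adjusted p = 0.0551 with an estimated correlation). Among them were Hmgcs1 at -0.21 ± 0.03 and -0.24 ± 0.03 and Dhcr7 at -0.26 ± 0.05 and -0.40 ± 0.05.

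Vessel, matrix and blood genes were lower in adults as well. Of 19 collagen and basement membrane genes, 17 were lower in females, 5 called and 9 adjusted over the list alone (adjusted p = 0.277 with an estimated correlation). In males 19 were lower, 11 and 12 (adjusted p = 0.0936 with an estimated correlation). Col4a1, a main basement membrane collagen, changed by -0.48 ± 0.09 in females and -0.68 ± 0.08 in males. All 10 endothelial genes were lower in both sexes, with 6 called and 9 adjusted over the list alone in males (camera's adjusted p = 5.03e-06, adjusted p = 0.172 with an estimated correlation). In females 0 were called by either adjustment (camera's adjusted p = 0.0155, adjusted p = 0.532 with an estimated correlation). The tight junction gene Cldn5 changed by -0.45 ± 0.11 in males. Mural genes were lower for 9 of 9 in males, among them Abcc9 at -0.34 ± 0.10 (camera's adjusted p = 0.0166, adjusted p = 0.457 with an estimated correlation). Meningeal genes were lower for 11 of 11, with Col1a1 at -0.91 ± 0.32 (camera's adjusted p = 0.00744, adjusted p = 0.558 with an estimated correlation). Neither list passed camera's test in females. All 7 genes of red blood cells were lower in both sexes, 6 past the threshold in females and 7 in males (adjusted p = 0.175 and adjusted p = 0.0551 with an estimated correlation). The globin Hbb stood at -1.80 ± 0.32 and -1.47 ± 0.31. These counts were the same adjusted over the list alone.

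Ribosomal protein genes were higher in adults. In females 93 were higher and 9 lower, with 44 called higher and 69 adjusted over the list alone. In males 96 were higher and 6 lower, with 64 and 71. The median log2 fold change was 0.20 and 0.23 (camera's adjusted p = 3.92e-22 and 2.41e-26, adjusted p = 0.175 and adjusted p = 0.0978 with an estimated correlation). Rpl5 rose by 0.27 ± 0.05 in females and 0.32 ± 0.05 in males. These families have near-identical copies in the genome, so the counts of single members are uncertain. Nuclear genes of oxidative phosphorylation were higher for 74 of 85 in males, where 13 were called higher and 1 lower and 16 and 1 when adjusted over the list alone (camera's adjusted p = 2.75e-07, adjusted p = 0.526 with an estimated correlation). Ndufa8, for example, rose by 0.22 ± 0.05. In females none was called. Interferon response genes were higher for 22 of 24 in females, 6 called and 9 adjusted over the list alone (camera's adjusted p = 2.03e-06, adjusted p = 0.175 with an estimated correlation). The list did not pass camera's test in males (adjusted p = 0.0678, 2 called higher and 1 lower). Ifi27 rose by 0.65 ± 0.10 in females and 0.46 ± 0.10 in males. All 14 heat shock and endoplasmic reticulum stress genes had positive fold changes in both sexes, 3 called in females and 2 in males, and 6 and 3 adjusted over the list alone (adjusted p = 0.277 and adjusted p = 0.267 with an estimated correlation). The chaperone Hspa1a rose by 0.73 ± 0.21 in females. Glucocorticoid response genes were higher for 13 of 16 in females, 4 called and 5 adjusted over the list alone (camera's adjusted p = 0.00150, adjusted p = 0.277 with an estimated correlation). Fkbp5, which dampens the glucocorticoid receptor, rose by 0.31 ± 0.06 in females and 0.25 ± 0.06 in males, where the list did not pass (camera's adjusted p = 0.104).

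Genes of DNA methylation and chromatin were lower for 15 of 21 in females, 4 called lower and 1 higher, and for 17 of 21 in males, 6 and 1, with the same counts adjusted over the list alone (adjusted p = 0.175 and adjusted p = 0.0936 with an estimated correlation). The de novo methyltransferase Dnmt3a changed by -0.28 ± 0.04 and -0.30 ± 0.04, and Tet1, which oxidises methylated cytosine, by -0.31 ± 0.06 and -0.43 ± 0.05. Glutamate receptor genes were lower for 17 of 23 in females, 4 called by either adjustment (camera's adjusted p = 0.00177, adjusted p = 0.277 with an estimated correlation), including Grin3a at -0.32 ± 0.05 and the obligatory NMDA receptor subunit Grin1 at -0.15 ± 0.03. In males Grin3a stood at -0.20 ± 0.05 and camera did not call the list (adjusted p = 0.122). Clock genes were higher for 13 of 16 in females, 3 called by either adjustment, and for 12 of 16 in males, 4 called and 5 adjusted over the list alone (adjusted p = 0.181 and adjusted p = 0.146 with an estimated correlation). Per2 rose by 0.27 ± 0.06 and 0.17 ± 0.06. Markers of inhibitory neurons were higher for 13 of 14 and 11 of 14, with 1 and 3 called and 4 and 3 adjusted over the list alone (adjusted p = 0.178 and adjusted p = 0.235 with an estimated correlation). Pvalb, a calcium buffer of fast-spiking interneurons, rose by 0.21 ± 0.06 in males. Astrocyte markers were higher for 11 of 12 in females, 3 called and 4 adjusted over the list alone (camera's adjusted p = 0.00163, adjusted p = 0.277 with an estimated correlation). Aldoc rose by 0.20 ± 0.06 in females and 0.24 ± 0.06 in males, where the list did not pass (camera's adjusted p = 0.122).

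Stress peptide genes passed camera's test in males, 11 of 14 higher with 5 called higher and 1 lower by either adjustment (camera's adjusted p = 0.0166, adjusted p = 0.130 with an estimated correlation). The growth factor Bdnf rose by 0.32 ± 0.08 in males. The list did not pass in females (camera's adjusted p = 0.196). Perineuronal net genes were lower for 10 of 12 in males, 4 called lower and 1 higher, 6 and 1 adjusted over the list alone (camera's adjusted p = 0.0259, adjusted p = 0.285 with an estimated correlation). The proteoglycan Ncan changed by -0.28 ± 0.04 in females and -0.29 ± 0.04 in males, and in females the list's mean of 0.02 lay opposite to its median of -0.08 and to camera's direction (adjusted p = 0.615). Genes of ethanol metabolism and oxidative stress were higher for 15 of 18 in females and 12 of 18 in males (camera's adjusted p = 0.0402 and 0.0486, adjusted p = 0.439 and adjusted p = 0.502 with an estimated correlation). Sod2, the mitochondrial superoxide dismutase, rose by 0.15 ± 0.02 in males. The other lists passed camera's test in neither sex. Of these, microglial genes gave camera's adjusted p = 0.625 in females and 0.676 in males, choroid plexus genes 0.404 and 0.253, striatal neuron genes 0.192 and 0.0736, excitatory neuron genes 0.601 and 0.787, GABA receptors 0.206 and 0.787 and monoamine and opioid receptors 0.869 and 0.262. Innate immune genes gave 0.717 and 0.836, sex steroid genes 0.349 and 0.836, pituitary and hypothalamic genes 0.607 and 0.826, and the Y-linked and X-escape lists 0.442 and 0.826 and 0.398 and 0.816. Single called members of these lists included Ppp1r1b, the dopamine-regulated phosphatase inhibitor of striatal neurons, at 0.26 ± 0.09 and 0.33 ± 0.08 and the excitatory vesicular glutamate transporter Slc17a7 at -0.18 ± 0.04 in females. In males they included the microglial genes Tmem119 at -0.37 ± 0.12 and Csf1r at -0.24 ± 0.09. Camera called 19 of 35 lists in females and 20 in males, and 2 and 1 held with an estimated correlation. Fry, the other alternative, called 16 and 17. With only the groups without alcohol at either stage, PF VEH and FCL VEH, the counts of called genes were 94 in females and 377 in males.

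**Figure D3:**
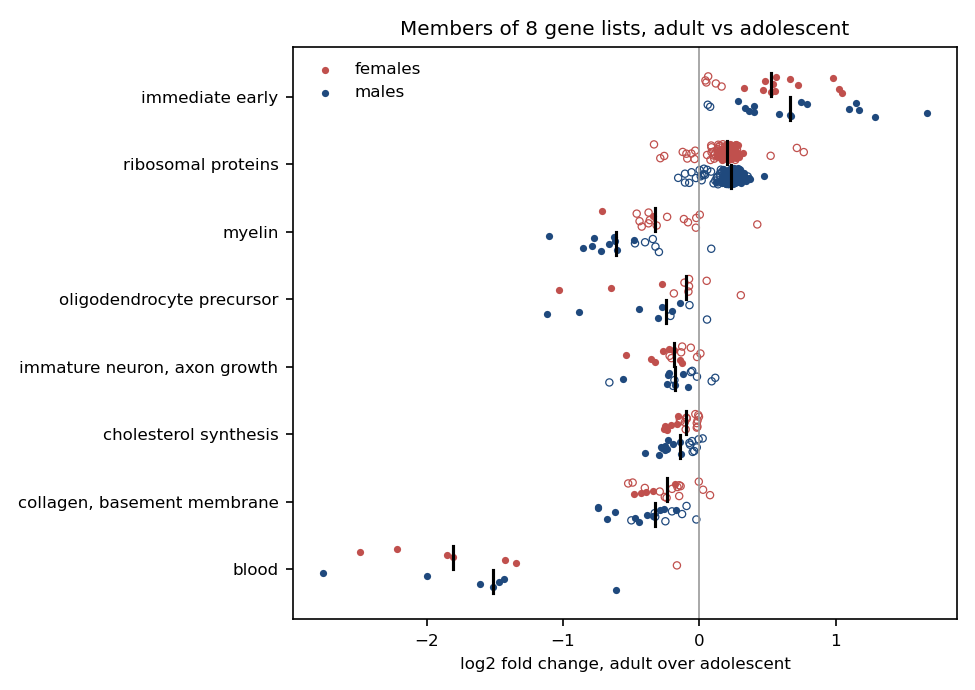
Log2 fold change of adults against adolescents for each member of 8 gene lists, with females in red and males in blue and bars at the median of a list. Filled points passed the threshold over all genes and open points did not, and the medians of the immediate early genes lie at 0.53 in females and 0.66 in males.

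The comparison of females with males asks which genes differ between the sexes at each age. At postnatal day 42, Xist was higher in females by 6.85 ± 0.33, 519.6 ± 119.6 CPM (SD, n = 34) against 13.3 ± 61.6 (n = 39). The Y-linked genes Eif2s3y (-7.50 ± 0.27), Ddx3y (-7.41 ± 0.28), Kdm5d (-7.21 ± 0.27) and Uty (-7.56 ± 0.29) were lower. The X-linked genes Eif2s3 (0.59 ± 0.03), Ddx3x (0.32 ± 0.03), Kdm6a (0.36 ± 0.04), Pbdc1 (0.40 ± 0.06) and Kdm5c (0.16 ± 0.03), which escape X inactivation, and Jpx (0.51 ± 0.10), an RNA that activates Xist, were higher in females. Dkc1, an X-linked gene of ribosome and telomerase assembly, was lower (-0.32 ± 0.06). Among autosomal genes with symbols, Fbxl22 (0.38 ± 0.09, adjusted p = 0.0342) was higher in females and Ankrd13a (-0.22 ± 0.05, adjusted p = 0.0498) and Scgb1c1 (-1.20 ± 0.29, adjusted p = 0.0499) were lower. Scgb1c1 stood at 1.73 ± 0.561 against 9.26 ± 42.9 CPM, where the male spread came from the olfactory transcripts of replicate 6 of the male PF VEH adolescents. C18h18orf63, chosen after its values were seen, was also lower (-0.63 ± 0.15, adjusted p = 0.0398), over both ages too (-0.58 ± 0.10, adjusted p = 2.00e-04). In all 24 genes passed at this age, 12 higher and 12 lower in females. At postnatal day 90, 17 genes passed, 9 higher and 8 lower, with Xist at 6.65 ± 0.35, Eif2s3 at 0.62 ± 0.03, Kdm6a at 0.51 ± 0.04 and Ddx3y at -7.12 ± 0.27. Each of the genes called at this age lies on the X or the Y chromosome. Over both ages 24 genes passed, among them the autosomal antiviral gene Oas1h at 1.17 ± 0.27 (adjusted p = 0.0184) and Paqr3 at -0.07 ± 0.02. Xist and its antisense neighbour share reads here, because the libraries do not mark strand.

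The X-escape list was higher in females for 6 of 6 and 6 of 6 at the earlier and later age, all called, and the Y-linked list lower for 4 of 4 and 4 of 4, all called. These calls held with an estimated correlation (adjusted p = 2.90e-27 and 2.79e-24 at day 42). In adolescents 16 of 16 myelin genes were lower in females by a median of -0.42, 0 called over all genes and 14 adjusted over the list alone (camera's adjusted p = 7.61e-18, adjusted p = 0.0948 with an estimated correlation). All 10 precursor genes were lower, 2 adjusted over the list alone (adjusted p = 0.0948 with an estimated correlation). All 17 immediate early genes lay on the higher side in adolescent females, 0 called and 2 adjusted over the list alone (adjusted p = 0.387 with an estimated correlation). In the test of the difference between the sexes in their change with age, edgeR called 0 genes, with 1063 at an unadjusted p under 0.05, while DESeq2 called 10. Its smallest p belonged to Scgb1c1 (1.79 ± 0.41, adjusted p = 0.424), Adgrg6 (1.12 ± 0.27) and Slc27a2 (2.57 ± 0.65). In the same test all 16 myelin genes had a positive value, with a median of 0.33 and none called by either adjustment (camera's adjusted p = 1.81e-08, adjusted p = 0.673 with an estimated correlation). Of the oxidative phosphorylation genes 75 of 85 had a negative one (adjusted p = 0.673 with an estimated correlation). The larger number of age calls in males is therefore not shown to be a difference between the sexes.

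The comparison of prenatal ethanol with pair-feeding asks what the exposure changed beyond restricted intake, and was made in each sex and age over both adolescent conditions. In adolescent females Slc25a26, the mitochondrial carrier of S-adenosylmethionine, differed by 0.40 ± 0.08, 23.2 ± 4.40 CPM (SD, n = 10) against 17.5 ± 1.51 (n = 12), with an adjusted p of 0.175. Gpatch11 differed by 0.24 ± 0.05, 38.2 ± 3.58 against 32.2 ± 2.09 CPM, adjusted p = 0.280. These and C5h8orf34 (0.31 ± 0.07) had the smallest p, and none passed the threshold. Without replicate 1 of the female PAE VEH adolescents, Slc25a26 passed. All 17 immediate early genes were on the higher side in PAE with a median of 0.30 (camera's adjusted p = 1.15e-06, adjusted p = 0.837 with an estimated correlation). On the lower side were 88 of 97 ribosomal protein genes (adjusted p = 0.862 with an estimated correlation) and 20 of 23 interferon response genes, 2 of them adjusted over the list alone (adjusted p = 0.837 with an estimated correlation). In adult females Pdp1, a phosphatase that activates pyruvate dehydrogenase, differed by 0.37 ± 0.08, 103.4 ± 8.27 CPM (SD, n = 11) against 80.6 ± 14.6 (n = 12), adjusted p = 0.5004. The uncharacterised RNAs LOC134482709 (-2.94 ± 0.59) and LOC134479317 (-0.92 ± 0.19) had a smaller p. In this stratum all 16 myelin genes were lower in PAE, with a median of -0.69, and 14 passed when adjusted over the list alone (camera's adjusted p = 9.80e-18, adjusted p = 0.423 with an estimated correlation). The group PF VEH here holds the library with the fewest genes detected.

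In adolescent males the ciliary rootlet gene Crocc differed by -0.44 ± 0.09, 16.1 ± 2.75 CPM (SD, n = 13) against 21.8 ± 3.79 (n = 13), adjusted p = 0.503. Xist (3.48 ± 0.79) and Cyp2a3 (-6.65 ± 1.52) followed the single libraries that carried those transcripts, replicate 4 of the male PAE VEH and replicate 6 of the male PF VEH adolescents. All 16 myelin genes were on the higher side in PAE, median 0.30 (camera's adjusted p = 7.53e-05, adjusted p = 0.678 with an estimated correlation), and 10 of 12 microglial genes (adjusted p = 0.678 with an estimated correlation). A fit of all libraries called 65 genes in this stratum, 64 of them lower in PAE, and without replicate 6 of the male PF VEH adolescents 1 gene. In adult males Angpt1, a vessel-stabilising growth factor, differed by -0.83 ± 0.18, 6.04 ± 1.77 CPM (SD, n = 10) against 10.6 ± 3.88 (n = 13), adjusted p = 0.944, next to Rhof (0.23 ± 0.06) and Ror2 (-0.82 ± 0.23). All 22 interferon response genes were on the lower side, median -0.28 (camera's adjusted p = 5.85e-04, adjusted p = 0.627 with an estimated correlation), as were all 11 meningeal genes (adjusted p = 0.627 with an estimated correlation). For this comparison edgeR called 0 genes in each of the 4 sex and age groups (828, 948, 825 and 891 at an unadjusted p under 0.05 in adolescent females, adult females, adolescent males and adult males). DESeq2 called 5, 1, 1 and 0 in the same order. In simulated counts, genes changed by 1.5-fold were recovered at 56.7%, 49.3%, 59.7% and 55.2% in the same order. Those changed by 2-fold were recovered at 71.2%, 81.8%, 69.7% and 80.3%.

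Set against the freely fed group, prenatal ethanol was compared with rats whose dams had not been restricted. It shares its PAE libraries with the comparison above. In adolescent females Tmem44 differed by 0.26 ± 0.06, 28.4 ± 2.14 against 23.7 ± 1.82 CPM, adjusted p = 0.214, and Angptl4, an inhibitor of lipoprotein lipase, by 0.75 ± 0.16, 5.57 ± 1.37 against 3.31 ± 0.801 CPM, adjusted p = 0.214. LOC134479834, a transcribed pseudogene, differed by 1.62 ± 0.31 (adjusted p = 0.179) and passed without replicate 1 of the female PAE AAE adolescents or without replicate 5 of the female FCL AAE adolescents. Of the immediate early genes 15 of 17 were higher, 5 adjusted over the list alone, with a median of 0.39 (camera's adjusted p = 1.34e-08, adjusted p = 0.455 with an estimated correlation). Of the glucocorticoid response genes 13 of 16 were higher, 2 adjusted over the list alone (adjusted p = 0.426 with an estimated correlation). In adult females Insig1, which restrains sterol synthesis, differed by -0.28 ± 0.06, 95.5 ± 7.75 against 115.5 ± 10.4 CPM, adjusted p = 0.301, and Olfml2b by -0.57 ± 0.12, 8.52 ± 2.10 against 12.6 ± 2.50 CPM, adjusted p = 0.355. The pseudogene Rcn1-ps1 differed by 1.31 ± 0.27. All 16 myelin genes were lower in PAE, 10 adjusted over the list alone, with a median of -0.55 (camera's adjusted p = 1.42e-10, adjusted p = 0.312 with an estimated correlation). So were all 11 meningeal genes (median -0.85, adjusted p = 0.312 with an estimated correlation). The FCL side here holds a library with 1529 CPM of the fibroblast collagen Col1a1.

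In adolescent males the dystrophin-complex gene Sntb2 differed by -0.41 ± 0.09, 17 ± 3.34 against 22.5 ± 2.58 CPM, adjusted p = 0.634, and Sox7, a transcription factor of endothelial cells, by -0.99 ± 0.23, 0.862 ± 0.379 against 1.71 ± 0.576 CPM, adjusted p = 0.634. All 7 blood genes were lower in PAE, 7 adjusted over the list alone, with a median of -1.41 (camera's adjusted p = 4.15e-10, adjusted p = 0.146 with an estimated correlation). So were all 10 endothelial genes, 5 adjusted over the list alone (adjusted p = 0.228 with an estimated correlation). In adult males Cwc27, a splicing factor, differed by -0.40 ± 0.09, 8.24 ± 1.47 against 10.6 ± 1.65 CPM, adjusted p = 0.597, and Zfp219 by 0.32 ± 0.08, 24.8 ± 2.79 against 20.1 ± 3.002 CPM, adjusted p = 0.9991. There 6 of 6 blood genes were higher in PAE, 5 adjusted over the list alone, with a median of 1.32 (camera's adjusted p = 0.0158, adjusted p = 0.797 with an estimated correlation). For this comparison edgeR called 0 genes in each of the 4 sex and age groups (779, 1157, 1017 and 733 at an unadjusted p under 0.05 in adolescent females, adult females, adolescent males and adult males). DESeq2 called 1, 2, 1 and 0 in the same order.

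The freely fed and pair-fed groups were compared to read the effect of the feeding regime alone. In adolescent females the transcription factor Klf6 differed by 0.27 ± 0.06, 59.9 ± 5.12 against 49.6 ± 5.33 CPM, adjusted p = 0.784, Tatdn3 by -0.43 ± 0.10 and Sema4b, a semaphorin, by -0.30 ± 0.07. Ribosomal protein genes were lower in FCL for 87 of 97 (camera's adjusted p = 3.83e-09, adjusted p = 0.533 with an estimated correlation), and all 12 astrocyte genes were lower (adjusted p = 0.485 with an estimated correlation). Choroid plexus genes were higher for 8 of 9, 5 adjusted over the list alone, with a median of 1.74 (adjusted p = 0.485 with an estimated correlation). Ttr, the most abundant choroid plexus transcript, reached 1822 CPM in replicate 3 of the female FCL AAE adolescents against a median of 37.6 over all libraries. In adult females Arpin, an inhibitor of the Arp complex of actin nucleation, differed by -0.43 ± 0.09, 9.16 ± 1.46 against 12.3 ± 1.63 CPM, adjusted p = 0.244, and the low-count pseudogene LOC120094461 by 3.22 ± 0.60 (adjusted p = 0.112). LOC120094461 passed when replicate 2 or 5 of the female FCL VEH adults or replicate 5 of the female FCL AAE adults was left out. Arpin passed without replicate 5 of the female FCL VEH adults. All 11 meningeal, 19 collagen, 12 microglial and 12 striatal neuron genes were higher in FCL, 6 of the last adjusted over the list alone (adjusted p = 0.509 with an estimated correlation for each of the 4 lists). The FCL AAE group includes the library with 258 CPM of Omp. In adolescent males Nat8f3 differed by 0.43 ± 0.09, 61.1 ± 12.8 against 45.4 ± 7.93 CPM, adjusted p = 0.625, and Cyp2a3 (-7.11 ± 1.60) and Umodl1 (-4.33 ± 0.98) followed the olfactory transcripts of a single PF library. All 7 blood genes were higher in FCL (camera's adjusted p = 2.51e-04, adjusted p = 0.692 with an estimated correlation). In adult males Prrx1, a homeobox gene of mesenchymal cells, differed by -0.55 ± 0.13, 5.73 ± 0.862 against 8.33 ± 2.55 CPM, adjusted p = 0.9996, and Iftap by 0.42 ± 0.10. All 11 meningeal genes were lower in FCL (adjusted p = 0.755 with an estimated correlation). For this comparison edgeR called 0 genes in each of the 4 sex and age groups (954, 1116, 686 and 817 at an unadjusted p under 0.05 in adolescent females, adult females, adolescent males and adult males). DESeq2 called 0, 4, 1 and 0 in the same order.

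Adolescent alcohol was compared with water over the 3 prenatal conditions, to read the effect shortly and weeks after the exposure. In adolescent females Cacng5, an AMPA receptor regulatory protein, differed by -0.47 ± 0.11, 10.8 ± 2.22 CPM (SD, n = 17) against 14.7 ± 3.84 (n = 17), adjusted p = 0.9994, with Isg20l1 at 0.55 ± 0.14 and Thsd7b at -0.37 ± 0.10. Cholesterol synthesis genes were lower after alcohol for 18 of 19, 1 adjusted over the list alone, with a median of -0.10 (camera's adjusted p = 3.86e-10, adjusted p = 0.449 with an estimated correlation). So were oxidative phosphorylation genes for 78 of 83 (adjusted p = 0.855 with an estimated correlation) and striatal neuron genes for 10 of 12 (adjusted p = 0.449 with an estimated correlation). In adult females Prdx1l1 differed by 0.46 ± 0.10, 13.7 ± 3.47 against 9.99 ± 1.61 CPM, adjusted p = 0.507, Pogk by 0.24 ± 0.06, 47 ± 5.93 against 39.6 ± 3.71 CPM, adjusted p = 0.507 and Arhgap36 by 2.15 ± 0.49. Prdx1l1 is a near copy of the peroxiredoxin gene Prdx1, which makes its counts uncertain. Ribosomal protein genes were higher for 91 of 97, median 0.18 (camera's adjusted p = 4.97e-13, adjusted p = 0.465 with an estimated correlation). GABA receptor genes were lower for 13 of 14, 6 adjusted over the list alone, median -0.15 (camera's adjusted p = 4.69e-06, adjusted p = 0.211 with an estimated correlation). In adolescent males Mthfd1l, an enzyme of mitochondrial folate metabolism, differed by 0.24 ± 0.05, 26.2 ± 2.88 against 22.2 ± 2.41 CPM, adjusted p = 0.485. The interneuron transcription factor Dlx1 differed by 0.22 ± 0.05, 23.7 ± 3.24 against 20.2 ± 1.81 CPM, adjusted p = 0.900. There 84 of 98 ribosomal protein genes were higher, median 0.08 (camera's adjusted p = 1.97e-11, adjusted p = 0.846 with an estimated correlation). In adult males Ccdc137 differed by 0.28 ± 0.07, 11.3 ± 1.45 against 9.41 ± 1.39 CPM, adjusted p = 0.9998. Immediate early genes were higher for 15 of 17 (camera's adjusted p = 1.43e-08, adjusted p = 0.542 with an estimated correlation). All 10 endothelial genes were higher, 1 adjusted over the list alone (adjusted p = 0.542 with an estimated correlation), and all 12 microglial genes were lower (adjusted p = 0.542 with an estimated correlation). For this comparison edgeR called 0 genes in each of the 4 sex and age groups (567, 1394, 879 and 631 at an unadjusted p under 0.05 in adolescent females, adult females, adolescent males and adult males). DESeq2 called 0, 0, 1 and 0 in the same order. Genes changed by 1.5-fold in counts simulated for this comparison were recovered at 65.7%, 68.7%, 80.6% and 70.1%, in the same order.

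Rats with both exposures (PAE AAE) were compared with the pair-fed water group (PF VEH) of their sex and age. In adolescent females Gpatch11 differed by 0.32 ± 0.07, 39.0 ± 5.01 CPM (SD, n = 5) against 31.3 ± 2.02 (n = 6), adjusted p = 0.9999. All 17 immediate early genes were on the higher side, median 0.39 (camera's adjusted p = 2.94e-10, adjusted p = 0.480 with an estimated correlation). Meningeal genes had a median of 0.03 and a mean of 0.00 there, with members on both sides of 0 (camera's adjusted p = 8.17e-04, adjusted p = 0.972 with an estimated correlation). In adult females Prcd differed by 0.82 ± 0.19, 10.03 ± 1.52 against 5.66 ± 1.95 CPM, adjusted p = 0.458, and Dusp7, a phosphatase of ERK kinases, by -0.40 ± 0.09, 78.8 ± 6.07 against 104.1 ± 17.7 CPM, adjusted p = 0.458. Heat shock and endoplasmic reticulum stress genes were higher for 12 of 14, 4 adjusted over the list alone (camera's adjusted p = 0.00139, adjusted p = 0.799 with an estimated correlation). Ribosomal protein genes were higher for 86 of 97 (camera's adjusted p = 9.18e-05, adjusted p = 0.910 with an estimated correlation). In adolescent males Fbxw8, a subunit of a neuronal ubiquitin ligase, differed by 0.38 ± 0.08, 59.7 ± 2.73 CPM (SD, n = 6) against 45.9 ± 2.31 (n = 7), adjusted p = 0.219. Stom (-4.89 ± 1.10) and Cyp2a3 (-8.90 ± 2.01) followed the PF VEH library with olfactory transcripts. Without that library Cyp2a3 stood at 1.41. All 16 myelin genes were on the higher side, median 0.77 (camera's adjusted p = 3.51e-13, adjusted p = 0.698 with an estimated correlation). In adult males Sh2d3c, a signalling adaptor, differed by 0.50 ± 0.11, 32.9 ± 4.51 against 23.3 ± 3.60 CPM, adjusted p = 0.665. Angpt1 differed by -1.02 ± 0.24, 6.23 ± 2.04 against 12.7 ± 3.89 CPM, adjusted p = 0.665. All 6 X-escape genes were on the lower side (camera's adjusted p = 0.00622, adjusted p = 0.0784 with an estimated correlation). For this comparison edgeR called 0 genes in each of the 4 sex and age groups (368, 1461, 1195 and 1250 at an unadjusted p under 0.05 in adolescent females, adult females, adolescent males and adult males). DESeq2 called 0, 2, 0 and 0 in the same order.

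The interaction of prenatal and adolescent alcohol asks whether the later exposure acted differently in PAE than in PF rats. In adult females the genes with the smallest p were Cwh43 (3.54 ± 0.82), Mfrp (-6.96 ± 1.63) and Sostdc1 (-8.48 ± 2.01), each with an adjusted p of 0.739. All 9 choroid plexus genes were lower, 6 adjusted over the list alone, with a median of -4.71 (camera's adjusted p = 6.82e-04, adjusted p = 0.738 with an estimated correlation). Ttr stood at 1944 CPM in replicate 4 of the PF AAE and at 1596 and 1475 in replicates 6 and 2 of the PAE VEH adults. In adult males Ccn4 had the smallest p (2.46 ± 0.61, adjusted p = 0.995). There 93 of 97 ribosomal protein genes were higher, median 0.38 (camera's adjusted p = 8.01e-22, adjusted p = 0.315 with an estimated correlation), and so were 81 of 84 oxidative phosphorylation genes (adjusted p = 0.360 with an estimated correlation). Immediate early genes were lower for 14 of 17 (adjusted p = 0.315 with an estimated correlation). In adolescent females Prss52 (1.64 ± 0.41, adjusted p = 0.945) and in adolescent males Nt5c3b (-0.40 ± 0.11) and Ano2 (5.29 ± 1.47), each with an adjusted p of 1, were among the genes with the smallest p. Ano2, a chloride channel of olfactory neurons, followed the same olfactory library. For this comparison edgeR called 0 genes in each of the 4 sex and age groups (726, 1178, 353 and 586 at an unadjusted p under 0.05 in adolescent females, adult females, adolescent males and adult males). DESeq2 called 0, 1, 1 and 0 in the same order. Simulated interactions of 2-fold were recovered at 57.6%, 24.2%, 51.5% and 51.5%, in the same order.

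Whether an exposure acted differently in females and males was tested directly. For prenatal ethanol against pair-feeding in adolescents, Slc25a26 differed between the sexes by 0.52 ± 0.12 (adjusted p = 0.123), and Xist by -3.37 ± 0.73, which follows the male PAE VEH library with Xist. Immediate early genes were higher in females than in males for 17 of 17, median 0.32 (camera's adjusted p = 1.45e-05, adjusted p = 0.871 with an estimated correlation). Myelin genes were lower for 16 of 16 (adjusted p = 0.898 with an estimated correlation). For prenatal ethanol in adults, Asah2, a ceramidase, differed by -0.81 ± 0.21 (adjusted p = 0.906) and Aldh3b2l1 by 6.18 ± 1.53. Myelin genes were lower for 16 of 16, median -0.57 (camera's adjusted p = 2.73e-08, adjusted p = 0.710 with an estimated correlation). For adolescent alcohol in adolescents, Avp, the vasopressin gene (4.73 ± 1.20), Cacng5 (-0.65 ± 0.17) and Sp9 (-0.98 ± 0.27), each with an adjusted p of 1, had the smallest p. Oxidative phosphorylation genes were lower for 82 of 85 (camera's adjusted p = 1.93e-09, adjusted p = 0.843 with an estimated correlation). For adolescent alcohol in adults, LOC103694537 (3.84 ± 0.82, adjusted p = 0.159), Kdm5d (2.86 ± 0.69) and Ddx3y (2.70 ± 0.66) are Y-linked. Replicate 1 of the female FCL AAE adults held 46.3 CPM of Y-linked genes. Ribosomal protein genes were higher for 92 and lower for 10, median 0.21 (camera's adjusted p = 7.65e-15, adjusted p = 0.526 with an estimated correlation). For these tests edgeR called 0 genes each (638 and 997 at an unadjusted p under 0.05 for prenatal ethanol in adolescents and adults, 603 and 1057 for adolescent alcohol). DESeq2 called 5, 8, 3 and 4 in the same order. For the other exposure comparisons a difference between the sexes was not tested.

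The authors' comparisons name neither sex nor age beside an exposure, and which libraries and tool they rest on is not given in the sources used here. Comparisons over all libraries were therefore added after the files had been read. Vip, the vasoactive intestinal peptide of a class of cortical interneurons (chromosome 1, 44470232 to 44478561), was higher in PAE than in PF by 0.21 ± 0.04, 45.9 ± 6.73 CPM (SD, n = 44) against 39.7 ± 5.45 (n = 50), adjusted p = 0.0239. It was higher than in FCL by 0.22 ± 0.04, where the FCL mean was 39.4 ± 6.25 (n = 50), adjusted p = 0.00805. Against PF it was not called with 2 surrogate variables (adjusted p = 0.0778). Both comparisons use the same PAE libraries. Tnfaip8l3, which carries phosphoinositide lipids (chromosome 8, 63309683 to 63351687), was higher in PAE than in FCL by 0.23 ± 0.05, 11.7 ± 2.18 against 10.01 ± 1.48 CPM, adjusted p = 0.0395. It was not called with 2 surrogate variables (adjusted p = 0.0544) or without the low-count filter (adjusted p = 0.0536). The uncharacterised LOC134479317, chosen after its values were seen, was lower in PAE than in PF (-0.56 ± 0.09, adjusted p = 5.08e-04) and than in FCL (-0.53 ± 0.09, adjusted p = 0.00159). The transcribed pseudogene LOC134479834, chosen likewise, was higher than in PF (0.75 ± 0.15, adjusted p = 0.0239). These are all of the called genes, 3 against PF and 3 against FCL, with 1532 and 1066 at an unadjusted p under 0.05, where DESeq2 called 26 and 23. Cry1, a repressor of the circadian clock (chromosome 7, 20417526 to 20481791), was higher after adolescent alcohol by 0.24 ± 0.04, 15.3 ± 2.83 CPM (SD, n = 72) against 12.9 ± 2.52 (n = 72), adjusted p = 0.00722. It was the only gene called there, with 1524 at an unadjusted p under 0.05, while DESeq2 called 12. FCL against PF gave 0 genes in edgeR, 815 at an unadjusted p under 0.05 and 2 called by DESeq2. The smallest p belonged to Hs3st5, a heparan sulphate sulphotransferase, at 0.25 ± 0.06 (adjusted p = 0.510).

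Among the lists in the pooled comparisons, inhibitory neuron genes were higher in PAE than in FCL for 10 of 14, 1 called and 3 adjusted over the list alone, with a median of 0.07 (camera's adjusted p = 1.13e-05, adjusted p = 0.0180 with an estimated correlation). Besides Vip, the neuropeptide gene Tac3 stood at 0.21 ± 0.07 and Dlx1 at 0.11 ± 0.04, neither past the threshold over all genes. Stress peptide genes were higher for 10 of 14, 2 adjusted over the list alone (camera's adjusted p = 1.32e-04, adjusted p = 0.0183 with an estimated correlation). Adcyap1, the peptide PACAP, stood at 0.19 ± 0.05 and Bdnf at 0.22 ± 0.07. Without the 5 libraries, the estimated correlation gave adjusted p = 0.0990 for both lists. Camera's smallest p in this comparison was that of immediate early genes, higher for 13 of 17. Its adjusted p was 1.21e-07, or 0.294 with an estimated correlation. Camera also called heat shock and endoplasmic reticulum stress genes (12 of 14 higher) and glucocorticoid response genes (14 of 16 higher). Interferon response genes were called lower (23 of 24). None of these held with an estimated correlation. In the same comparison markers of neighbouring tissue were lower in PAE, striatal neuron genes for 12 of 12, 5 adjusted over the list alone (camera's adjusted p = 0.00162, adjusted p = 0.592 with an estimated correlation), meningeal genes for 11 of 11 (camera's adjusted p = 1.41e-04, adjusted p = 0.625 with an estimated correlation) and choroid plexus genes for 9 of 9 (camera's adjusted p = 0.0672). Against PF all 24 interferon response genes were lower in PAE, 1 adjusted over the list alone, with a median of -0.13 (camera's adjusted p = 0.00137, adjusted p = 0.780 with an estimated correlation). All 7 blood genes were lower there too, median -0.53 (camera's adjusted p = 0.0176, adjusted p = 0.839 with an estimated correlation), as were 11 of 11 meningeal and 15 of 16 myelin genes, which did not pass (camera's adjusted p = 0.113 and 0.0618). After adolescent alcohol 16 of 17 immediate early genes were higher, 6 adjusted over the list alone, with a median of 0.16 (camera's adjusted p = 1.80e-06). GABA receptor genes were lower for 12 of 14, 2 adjusted over the list alone (camera's adjusted p = 1.80e-06). Heat shock and endoplasmic reticulum stress genes were higher for 13 of 14, 5 adjusted over the list alone. With an estimated correlation these gave adjusted p = 0.476, 0.230 and 0.428. Markers of other cells also lay to one side. Blood genes were higher for 7 of 7, 5 adjusted over the list alone, with a median of 0.60 (camera's adjusted p = 0.00453). So were myelin genes for 16 of 16 and endothelial genes for 10 of 10 (camera's adjusted p = 0.00145 and 0.0267). Striatal neuron genes were lower for 11 of 12, 1 adjusted over the list alone (camera's adjusted p = 0.00171). Each of these lists gave adjusted p = 0.687 with an estimated correlation.

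**Figure D4:**
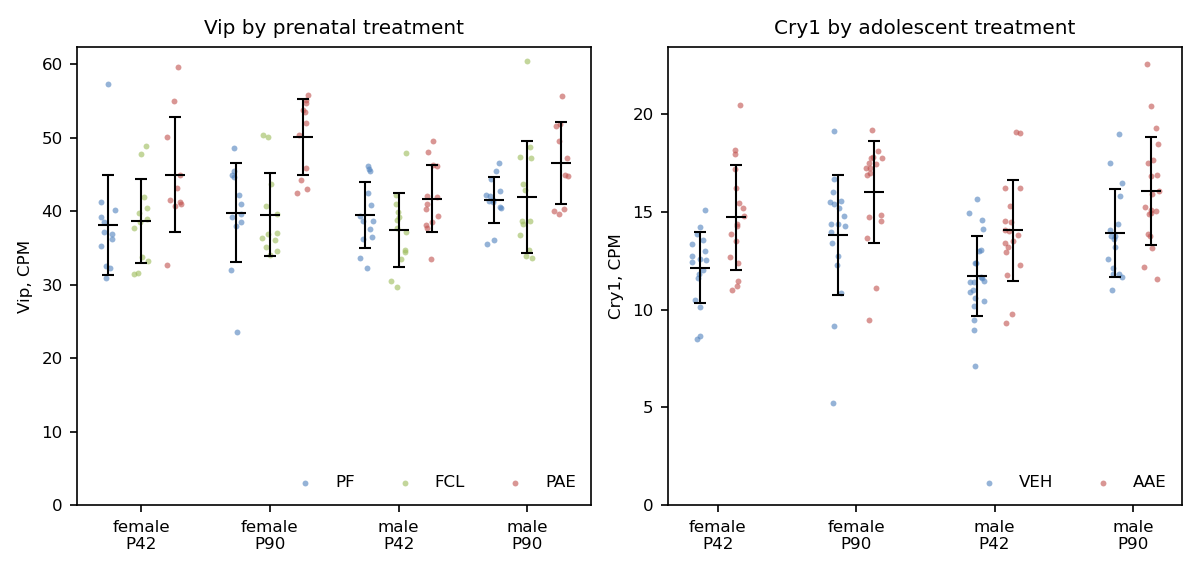
Vip by prenatal condition and Cry1 by adolescent condition in CPM, with 1 point per library and the mean ± SD of each condition within each sex and age. Over all libraries Vip averaged 45.9 in PAE and 39.7 in PF, and Cry1 15.3 after alcohol and 12.9 after water.

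The authors' deposited table holds 6 comparisons. For adolescents against adults, the authors' deposited table lists 4842 genes with an adjusted p under 0.05, 2403 higher and 2439 lower in adolescents, of which 4330 were among the 4475 genes called here over both sexes, all in the same direction. For females against males, 24 of the 28 genes in the authors' deposited table were called here. For adolescent alcohol, the authors' deposited table gives Cry1 at 0.25 (adjusted p = 0.00578) and Cntf, a neurotrophic cytokine, at 0.32 (adjusted p = 0.0158). For prenatal ethanol, the authors' deposited table lists 3 genes against PF, 3 of them called here, with Vip at 0.21 (adjusted p = 0.0181). Against FCL, the authors' deposited table lists 5 genes, 3 of them called here, Vip at 0.22 (adjusted p = 0.00950), Tnfaip8l3 at 0.23 (adjusted p = 0.0255) and LOC134479317 at -0.53 (adjusted p = 6.19e-04), and also the protocadherin Pcdhga12 at 0.25 (adjusted p = 0.0255) and Cfap206 at -0.87 (adjusted p = 0.00970). It lists 0 genes for PF against FCL, with 958 at an unadjusted p under 0.05 in the authors' deposited table.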

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

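The tests of the sex markers below, the female library without Xist as a male library and both tests of the male library with Xist, were chosen after the result was seen, while the tests of a single X chromosome, of the olfactory genes and of the myelin genes were written down before it.

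Of 96 groups of library values examined with Dixon's test, 20 had a value past it, where chance would give about 1 in 20 groups, or 4.8. Genes detected were 28008 in replicate 4 of the female PF VEH adolescents, 15631 in replicate 6 of the female PF VEH adults and 26658 in replicate 6 of the male PF VEH adolescents. The median correlation with all other libraries of the series was 0.8781 in that female adult and 0.9507 in that male adolescent. It was 0.9338 in replicate 1 of the female FCL AAE adults, 0.9704 in replicate 6 of the female PF AAE adolescents and 0.9732 in replicate 4 of the male PAE AAE adults. It was 0.9798 in replicate 7 of the male PAE VEH adolescents, 0.9732 in replicate 1 of the male PF AAE adolescents and 0.9752 in replicate 4 of the male PF AAE adults. Total counts, in M, were 34.4 M in replicate 4 of the female FCL AAE adolescents, 25.3 in replicate 5 of the female PAE AAE adults, 31.3 in replicate 4 of the female PAE VEH adults, 24.6 in replicate 6 of the female PF AAE adults, 25.002 in replicate 3 of the male FCL AAE adults and 23.9 in replicate 6 of the male PF VEH adolescents. Past it were also the Xist (1302 CPM) and Y-linked (27.1) values given above, and Y-linked genes at 220.0 in replicate 6 of the male FCL AAE adolescents.

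In the fit of all libraries, 64 genes were called lower in PAE than in PF adolescent males with a median log2 fold change of -4.04 (SD 2.04), 10 of them among 13 tested markers of olfactory mucosa such as Omp and Cyp2a3, several of which were picked after the data were seen. Olfactory mucosa in replicate 6 of the PF VEH group is a likely source, since 63 of the genes peaked there and 0 were still called lower without it. That library held 398 CPM of Omp and 2371 of Cyp2a3, against medians of 0.0794 and 0.259 in the 142 libraries other than it and replicate 1 of the female FCL AAE adults. Of 14 markers written, 3 lie over 1 CPM in the median of those libraries and 0 belong to another list. Whether prenatal ethanol adds to this stays open, because the 56 genes tested without it (median -0.99) had been chosen for being lower in this comparison, which by itself favours a negative median.

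In adult males 10 of 16 myelin genes and 7 precursor genes were called lower than in adolescents. A smaller share of white matter in the tissue piece could lower them together. With the mean myelin level as a covariate Gpr17 went from -0.88 ± 0.09 to -0.60 ± 0.06. Enpp6 went from -1.12 ± 0.16 to -0.61 ± 0.09, and 5 precursor genes were still called lower. Myelin itself fell with age, so this cannot decide on the share. The myelin genes themselves moved apart, Ugt8 by -1.10 ± 0.16 and Ermn by 0.09 ± 0.16 without the covariate, and 11 of them differed with it (in both directions, as centring on their mean requires), which a uniform share alone does not give. With 2 surrogate variables 10 myelin genes were called and the median went from -0.61 to -0.60. Technical effects tied to age are not removed and stay open. For blood left in the tissue, 12 of 17 myelin and precursor genes were still called with a blood covariate, which leaves a part open.

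Sex markers went against the label in replicate 4 of the female PF AAE adolescents, which lacked Xist. It is unlikely to be a male library, because its Y-linked genes came to 0.331 CPM, where male libraries held at least 154.4. A single X chromosome is a candidate explanation, since Kdm5c, Pbdc1 and Jpx stood at a mean position of 1.15 between the female mean at 0 and the male mean at 1, which 0 of 66 other females reached. Replicate 4 of the male PAE VEH adolescents, with Xist, was not swapped with a female library of the series, as the highest Y-linked sum under a female label was 46.4 CPM. It could be mostly female RNA with some male RNA, because Eif2s3, Ddx3x and Kdm6a lay within 1.21 SD of such a mixture, with a male share of 13.9% from the Y-linked genes, and within 0.983 SD with the female share of 73.6% that Xist gives, so the share itself is uncertain.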

How the results depend on the processing

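Of the alternatives below, those for the comparisons over both sexes and ages and those without 5 libraries were chosen after the results were seen, and the others before. The counts of called genes moved by less than 1.5-fold in 39 of 39 comparisons without the 5 libraries and in 39 with RLE scaling, and in 4 of 4 interactions of sex with an exposure fitted within 1 age. Comparisons given below without another count had 0 called genes in edgeR as reported.

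With only PF VEH and FCL VEH, 94 genes changed with age in females against 1817 as reported and 377 against 2630 in males, and 12 against 24 differed by sex in adolescents and 11 against 17 in adults. Fewer libraries alone could lower these counts, and the cause was not tested. Fbxl22 in adolescents reversed from 0.38 to -0.033.

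DESeq2 called 30 genes by sex in adults against 17, 10 for sex by age, 5 and 8 for sex by prenatal ethanol in adolescents and adults, and 3 and 4 for sex by adolescent alcohol. Within a sex and age, its calls for the exposure comparisons were those given above, at most 5 genes. Over both sexes and ages it called 26 for PAE against PF, 23 for PAE against FCL, 2 for FCL against PF and 12 for AAE against VEH, where edgeR called 3, 3, 0 and 1. The cause was not tested.

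Without the low-count filter, 6 genes were called for sex by age, 1 and 2 for sex by adolescent alcohol in adolescents and adults, and 5 against 3 for PAE against PF over both sexes and ages. With 2 surrogate variables, 1 gene was called for sex by prenatal ethanol in adolescents and 1 for PAE AAE against PF VEH in adolescent males. The cause was not tested.

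In the fit of all libraries, PAE against PF gave 4 genes in adolescent females and 65 in adolescent males, and PAE against FCL 3, 2 and 1 in adolescent females, adult females and adolescent males. FCL against PF gave 4 in adult females and 61 in adolescent males, AAE against VEH 11 in adult females, and PAE AAE against PF VEH 12 in adult females, 1.2e+02 in adolescent males and 1 in adult males. In adolescent males the calls against PF may come from the olfactory transcripts of 1 PF VEH library, whose removal left 0 of the 64 lower genes of PAE against PF. For the other comparisons the cause was not tested.

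Leaving out 1 library moved 6 of 573 counts. As given above, they concerned Slc25a26 and LOC134479834 in adolescent females and LOC120094461 and Arpin in adult females. Cyp2a3 in PAE AAE against PF VEH adolescent males went from -8.90 to 1.41 without replicate 6 of PF VEH and to -9.65 without replicate 2 of PAE AAE, the range over single libraries. It was 1.41 without the 5 libraries, 1.45 in DESeq2 and 0.74 with surrogate variables.

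Over the 1131 tests of the gene lists in the 33 planned comparisons, 7 passed with an estimated correlation and 39 with fry, against 321 with the preset one. In the added comparison of PAE with FCL these were 2, 2 and 13 of 35. The adjusted p of Vip ran from 0.00262 to 0.0778 for PAE against PF, the last with 2 surrogate variables, and from 8.01e-04 to 0.0106 for PAE against FCL. That of Tnfaip8l3 ran from 0.00526 to 0.0544 and that of Cry1 from 4.95e-04 to 0.0136.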

Other observations

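The tests of the age changes in both sexes, of the share of inhibitory neurons and of the splits of comparisons with 0 called genes were chosen after the result was seen, and the other tests of this part before it.

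Some members of the gene lists that were not named above were also called with age. Grm2, a presynaptic glutamate receptor, changed by -0.43 ± 0.14 in females, Crhr1, the receptor of the stress peptide CRH, by -0.34 ± 0.06, and Crhbp, which binds CRH, rose by 0.28 ± 0.06 in females and 0.26 ± 0.06 in males. Htr2c, a serotonin receptor, rose by 0.31 ± 0.11 in males. The perineuronal net genes Hapln1 (-0.22 ± 0.05) and Vcan (-0.35 ± 0.09) were lower in adult males, where Bhlhe40, a clock repressor, rose by 0.24 ± 0.05.

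Of 1817 genes called with age in females, 1760 had the same sign in males, 96.9%, and 1094 were called in both, 1093 with the same sign. Of these 591 were higher, where unrelated lists would share 67, and 502 lower, where they would share 52. The correlation of the log2 fold changes was 0.354 over all genes and 0.812 over those called in females. Maturation of the cortex may underlie this, as a hypothesis, but a difference in collection or dissection between the ages would also act on both sexes and was not tested.

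Vip was higher in PAE than in PF in 4 of 4 sex and age groups, by 0.24 ± 0.09, 0.33 ± 0.09, 0.09 ± 0.07 and 0.17 ± 0.08 in adolescent females, adult females, adolescent males and adult males, which in part restates its call over these groups together. The other 13 inhibitory neuron genes had a median log2 fold change of 0.0382 (SD 0.0685) against PF. A larger share of all such neurons thus does not give the whole difference. With 12 of 14 of the list higher (camera's adjusted p = 0.00137, adjusted p = 0.108 with an estimated correlation) it may give a part. Against FCL it stays open, as the other 13 genes had a median of 0.0617 (SD 0.0673), 9 of them higher. The list's adjusted p with an estimated correlation, 0.0180 or 0.0990 without the 5 libraries, in part restates the rise of Vip. A larger Vip class alone would hardly show here and stays open. Reassigned labels gave at least as many calls in 3 of 21 splits each for PAE against PF and against FCL (highest other 38 and 58). Chance is not excluded for these counts.

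Cry1 was higher after adolescent alcohol by 0.27 ± 0.08, 0.22 ± 0.11, 0.26 ± 0.08 and 0.20 ± 0.08 in the same order of groups. A shift of the circadian clock could raise it, but of 15 other clock genes 1, Nr1d1, differed when adjusted over the list alone (-0.15 ± 0.04, adjusted p = 0.00122), which leaves this open. Collection times are not in the labels. Reassigned labels gave at least as many calls in 2 of 21 splits (highest other 239).

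For age only the real split of 21 reached the count (highest other 49 in females, 51 in males and 1 over both sexes). The same held for sex over both ages (highest other 1). With 21 splits no smaller share is possible, so chance is not firmly excluded. For sex within an age the counts, mostly X- and Y-linked genes, were reached in 2 of 21 splits (highest other 52), in adolescents and 5 of 21 splits (highest other 56), in adults. Sex by age, FCL against PF over both sexes and ages and the interactions of sex with an exposure had 0 called genes. All 21 of 21 splits reach this by construction and test nothing there. The highest count of another split was 5 for sex by age, 10 for FCL against PF, 8 and 1.8e+02 for sex by prenatal ethanol in adolescents and adults, and 0 and 2 for sex by adolescent alcohol.

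Within a sex and age each exposure comparison called 0 genes, which all 50 of 50 splits reach by construction, so these splits test nothing either. The highest count of another split, in adolescent females, adult females, adolescent males and adult males, was 3, 0, 1 and 150 for PAE against PF, 1, 1, 66 and 604 for PAE against FCL and 63, 0, 0 and 1 for FCL against PF. It was 432, 0, 76 and 0 for AAE against VEH, 5, 17, 44 and 448 for PAE AAE against PF VEH and 1.2e+02, 1, 0 and 4 for their interaction. Splits with many more calls than the real labels point to sample structure that the labels do not name, which was not tested.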
